A study of Mus musculus with 3 samples.

How the data were processed

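Neutrophils were taken from the peripheral blood of female C57BL/6J mice by magnetic negative selection, in which antibodies remove the other blood cells, and their RNA was profiled cell by cell with the 10x Genomics 3' v3 droplet assay. Mice received intraperitoneal injections, the first on day 0 and the others on days 2, 4, 7 and 9, per the labels' protocols. The injected agent was 50 μg of CpG ODN1826, a synthetic DNA that activates Toll-like receptor 9 and that serves in this schedule as a model of macrophage activation syndrome (MAS), a hyperinflammatory disease. The MAS library came from mice killed 1 day after the last injection and the Resolution library from mice left to recover for 3 weeks. The Control library has the treatment "None", while the protocol names DPBS as the vehicle. Each of the 3 libraries pooled the neutrophils of 4 mice before 16000 cells were loaded, so the mice within a library cannot be separated and each group is 1 library.

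The deposited matrices hold whole-number UMI counts (counts of distinct captured molecules) per gene and cell barcode, not scaled for depth. Per the submitters' processing notes, Cell Ranger 7.0.1, Seurat 4.1.1 and genome build mm10 were used, with no statement of which tool did which step. Of the stored entries, 4.88% in Control, 4.29% in MAS and 4.76% in Resolution were explicit zeros (2669047 of 57177778), so some entries had been set to 0 by a step that no header or label records. The 32285 gene symbols were the same in all 3 libraries. The matrices held 10940, 8598 and 11383 barcodes for Control, MAS and Resolution (30921 in all), against 10481, 8278 and 11001 cells (29760 in all) that the study states after quality control and removal of contaminated cells. The study's filter is not stated in numbers, and its 6 neutrophil populations are not recorded per cell in the matrices.

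Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept, which left 10910 Control, 8566 MAS and 11342 Resolution cells (30818 in all). The gene minimum removed 10, 25 and 6 barcodes and the mitochondrial maximum 27, 11 and 40. The kept cells were clustered together. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and a graph of 15 shared neighbours (edges under 1/15 removed) was divided by the Leiden method at resolution 1 with seed 0, giving 17 clusters. The tools were Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.

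Clusters were named from 12 lists of marker genes. A cluster took the name of another cell type when at least 3 of that type's markers had a UMI in at least 25% of its cells and in a share at least 3-fold that of all other cells. Otherwise it was called neutrophil when the median neutrophil marker reached 0.5 of its share in all cells. Clusters named as another type, and clusters with over 3-fold fewer UMIs per cell than their libraries' median, also needed a marker of the named type among their 10 leading genes. This naming by shares of cells replaced naming by summed counts after the clusters had been seen. It left 5 clusters unnamed, with 1.88% of Control, 4.17% of MAS and 3.07% of Resolution cells, and these entered no comparison of neutrophils. No cell was removed as a doublet, because the doublet detector Scrublet, run on each library, marked 0, 1 and 0 cells. That is far below the expected rate of 0.08 it was given, so doublets may remain among the cells.

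UMI counts as deposited were summed over the neutrophils of each library and divided by the library's neutrophil total and scaled to give CPM, the usual per-library count scale. Ratios between libraries are log2 ratios of CPM with 5 added to each value, and folds are ratios of CPM with nothing added. Before the data were examined, the following were fixed: the lists of 25 gene groups, the rules of size, the rule for naming genes and 27 alternatives to the processing. A gene was called higher or lower when the larger CPM was at least 10, the ratio with 5 added was at least 2-fold, and the 95% exact Poisson intervals of both CPM values did not overlap. Intervals of folds are exact conditional binomial (Clopper-Pearson) intervals, and those of shares of cells are exact binomial (Clopper-Pearson) intervals. All intervals, and the limits that a count of 0 allows (3 counts), are at 95% where a level applies and cover counting error only. The intervals of CPM and of folds treat UMIs as independent, so they are too narrow for genes whose UMIs sit in few cells. With 1 library per group no test between conditions was possible, no replicate check exists, and cells were not treated as replicates.

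For each gene list, members with a CPM of at least 5 in the larger library were taken, so a list that is higher in 1 library can have more members measured. Members at least 1.5-fold higher or lower with non-overlapping intervals were counted, and the list's median log2 ratio was placed among those of 10000 random lists of the same size matched on expression in 20 bins. A list was said to stand apart when its percentile was below 2.5 or above 97.5 and at least 5 members were measured, which describes these libraries and tests nothing. Because random lists carry the shift of all genes, a list can stand apart as lower with a median near 0 when the median gene was higher. Genes were named by rule: up to 12 with the highest and 12 with the lowest log2 ratio in each comparison against Control (6 and 6 for MAS against Resolution) among called genes with a CPM of at least 20, up to 2 members furthest up and 2 furthest down in each list, and 16 genes fixed by name. The rule leaves out mitochondrial, ribosomal, haemoglobin and immunoglobulin genes, markers of other cell types and gene models without a name. Members named from lists are called at 1.5-fold. Genes outside the rule are identified as such where they appear.

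Neutrophils were clustered again for the comparison of cluster sizes, with the 220 genes that differed by 2-fold in any comparison left out of the variable genes, at resolution 0.5. This gave 4 clusters. A clustering with all variable genes kept gave 6. Shares of single cells with a UMI were computed after thinning every cell to 1000 UMIs at random, and cells below that number were left out. Free RNA released by broken cells can give a UMI in a cell that does not express the gene, so each share stands beside that of monocytes and macrophages, and of platelets or megakaryocytes for Cd274. Genome positions come from GENCODE M21 on GRCm38, the same build as mm10, which held 196 of 197 named genes.

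The scripted steps were tested on simulated data drawn from the real means and totals. With 50 genes planted at each fold and 32285 genes in the step, the 2-fold rule recovered 48 genes planted at 3-fold and 50 at 5-fold for MAS against Control, 46 and 50 for Resolution against Control, and 49 and 49 for MAS against Resolution. Of genes planted at 2-fold it recovered 1, 5 and 2. It called 0 of 5703, 5890 and 5801 unchanged genes that passed the count minimum. The simulated counts hold counting error only and no spread between libraries, so this says nothing of false calls between real libraries. A list planted at 2-fold stood apart in each comparison, and so did 4, 8 and 4 of 100 lists of unchanged genes.

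The alternatives covered scaling (edgeR TMM factors, edgeR RLE size factors, totals without the 50 most abundant genes, every cell weighted equally, cells thinned to 1000 UMIs), filters on barcodes, doublets and other cell types, the added CPM, the CPM minimum, the fold, equal weighting of the neutrophil clusters with at least 50 cells in each library (4 of 6 with all variable genes kept), unmatched random lists, and the settings of the clusterings and of the thinning. A further 3 were chosen after seeing the data: leaving out cells above 1% haemoglobin UMIs, leaving out cells above 2 times the library's median UMIs, and counting entries stored as 0 as 1. Ahsp, Azu1, Mx1, Mx2 and Clec7a from the lists are not among the matrices' symbols and were not analysed here.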

Results

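Blood neutrophils of mice were profiled by single-cell RNA sequencing in 3 libraries, each pooled from 4 mice: Control, MAS (1 day after the last of the CpG injections) and Resolution (after 3 weeks of recovery). The design asks how neutrophils differ during CpG-induced macrophage activation syndrome and whether they return to the Control state afterwards. The matrices held 59225746 UMIs over 10940 barcodes for Control, 55462790 over 8598 for MAS and 63267708 over 11383 for Resolution. Median depth per barcode was 4860, 5923.5 and 4998 UMIs, with 1626, 1775.5 and 1705 genes. The neutrophil sums compared here held 53957365, 52203999 and 58116855 UMIs, so counting error was small for most named genes. For granule genes the intervals are too narrow, because few cells hold most UMIs. Camp had a UMI in 70 of 10303 Control neutrophils, with up to 370 UMIs in a cell, and Ltf in 244, with up to 206. With 1 library per group, no difference below could be compared with a spread between replicates, and each statement is about these libraries.

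Neutrophils made up 94.4% (95% interval 94.0 to 94.9) of Control, 93.5% (92.9 to 94.0) of MAS and 94.5% (94.0 to 94.9) of Resolution cells, which is 10303, 8006 and 10713 cells. Negative selection sets these shares in part, since it removes other cells before loading. Different clusters held most of them: 2 of the 9 neutrophil clusters, numbered 3 and 7, held 4137 and 2305 of the MAS neutrophils, against 96 and 31 in Control and 75 and 30 in Resolution. Monocytes and macrophages, which mature from a related blood lineage, made up 3.11%, 0.992% and 2.13% of Control, MAS and Resolution cells. Platelets or megakaryocytes made up 0.578%, 1.38% and 0.344%. Haemoglobin transcripts, the mark of red cells, differed within the neutrophil sums: the 4 haemoglobin genes together stood at 7.69 CPM (6.97 to 8.47) in Control, 370.9 (365.7 to 376.2) in MAS and 2.10 (1.74 to 2.51) in Resolution. The haemoglobin genes were chosen after their values were seen. In MAS, 11 cells above 1% haemoglobin UMIs carried most of this, and without them the level was 33.2 CPM (31.6 to 34.8). A haemoglobin UMI was present in 11.4% of MAS cells of cluster 3 and in 10.5% of cluster 7, and in 13.2%, 11.6%, 7.84%, 11.6%, 5.56%, 5.09% and 8.16% of MAS cells of neutrophil clusters 1, 2, 4, 5, 6, 8 and 10. The shares were 3.24% (cluster 4) to 11.4% (cluster 8, 44 cells) in Control and 0% (cluster 3) to 3.33% (cluster 7, 30 cells) in Resolution. Over all MAS barcodes, 58.8% of stored Hba-a1, 45.9% of Hba-a2 and 37.8% of Hbb-bt entries were zeros. The MAS haemoglobin values are thus those left after that step.

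In MAS neutrophils, transcripts of class I histocompatibility molecules, interferon response and the secondary granules were higher than in Control. H2-Q7, a nonclassical class I histocompatibility molecule, stood at 675.8 CPM in MAS and 23.5 in Control (28.8-fold, 27.2 to 30.5). Gbp2, an interferon-induced GTPase that acts against intracellular microbes, was 9.19-fold higher (8.83 to 9.58; 48.3 and 444.1 CPM in Control and MAS). Camp, the antimicrobial peptide cathelicidin of secondary granules, was 18.6-fold higher (17.6 to 19.6; 24.6 and 456.3 CPM). Cd274, which encodes the T cell inhibitory ligand PD-L1, was 4.18-fold higher (4.07 to 4.30; 113.4 and 474.3 CPM), while Ptgs2, the enzyme that starts prostaglandin synthesis, was 2.34-fold lower (2.27 to 2.41; 289.6 and 123.9 CPM).

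Of 6093 genes above the CPM minimum, 100 were higher and 45 lower in MAS than in Control. The median gene had a log2 ratio of -0.11, and scaling with TMM factors moved it to 0.04 and the calls to 131 higher and 24 lower (133 and 23 with RLE size factors). Of the 100 higher genes, 52 belonged to a fixed list, among them 17 of the interferon gamma list, 10 of MHC class I, 9 of secondary granules and 8 of the type I interferon list, and of the 45 lower genes 3 did. The 12 named genes with the highest ratios were H2-Q6, H2-Q7, Camp, Gbp4, Ngp, Ltf, Gbp8, Gbp5, Gbp2, Ifi47, H2-Q4 and Csta2. Gbp4 had 9 UMIs in Control and was 385-fold higher (203 to 844). H2-Q6 was 42.2-fold higher (38.0 to 47.0), Gbp5 17.9-fold, Gbp8 15.1-fold and the interferon-induced GTPase Ifi47 9.70-fold. Ngp, a secondary granule protein, was 13.6-fold higher (13.2 to 14.1), and the iron-binding granule protein Ltf 12.4-fold (11.5 to 13.3). H2-Q4 was 6.93-fold and Csta2, a cystatin, 11.5-fold higher. The H2-Q, Gbp and stefin and cystatin A genes have near-identical copies, so how UMIs were divided among members of each family is uncertain.

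The 12 named genes with the lowest ratios were Pde7b, Thbs1, Slc8a1, Pid1, Nup155, Cnnm2, Tmem132b, Arhgap18, Slc38a1, Acta2, Dock4 and Elmsan1. Pde7b, a phosphodiesterase that breaks down cyclic AMP, was 3.27-fold lower (3.15 to 3.39; 231.3 and 70.8 CPM in Control and MAS). Slc8a1, a sodium-calcium exchanger, was 4.17-fold lower (3.73 to 4.68), Nup155, a protein of the nuclear pore, 4.04-fold, and Thbs1, the matrix protein thrombospondin, 3.23-fold. The others were 2.52-fold to 3.82-fold lower, from Elmsan1 to Cnnm2. On GRCm38, H2-Q6 lies on chromosome 17 at 35424850 to 35430055 and H2-Q7 at 35439155 to 35443773. Camp, Ngp and Ltf lie on chromosome 9 at 109847379 to 109849617, 110419747 to 110423012 and 111019271 to 111042767. Gbp2 and Gbp5 lie on chromosome 3 at 142620602 to 142638008 and 142493978 to 142522344, and Gbp4 on chromosome 5 at 105115767 to 105139586. Cd274 lies on chromosome 19 at 29367455 to 29388095, Pde7b on chromosome 10 at 20398004 to 20725078 and Slc8a1 on chromosome 17 at 81373105 to 81738377. All are annotated as protein coding.

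Among the lists, all 19 measured members of the interferon gamma and GBP list were at least 1.5-fold higher in MAS, with a median log2 ratio of 1.75. Of these, 8 were below 5 CPM in Control and measured only because they were high in MAS, and with no CPM minimum 21 of 29 members were higher and 0 lower (median 1.30). The type I interferon list had 21 of 37 members higher and 0 lower (median 0.70). Zbp1, a sensor of nucleic acids, was 4.96-fold higher and Isg15, a ubiquitin-like protein, 1.75-fold, while Trim30d and Ddx58 had log2 ratios of -0.32 and -0.15. In the MHC class I list 17 of 21 members were higher and 0 lower (median 0.93). Secondary granule genes had 11 of 18 members higher and 0 lower (median 0.93). The NADPH oxidase and antimicrobial list had 4 of 14 higher and 0 lower (median 0.23), with Cybb, a subunit of the oxidase, 2.32-fold and Acod1, which makes itaconate, 1.79-fold higher. Smaller shifts put 3 further lists above the random range: NF-kB and immediate early genes (3 higher and 1 lower of 30, median 0.11), survival and apoptosis (2 and 1 of 20, median 0.12) and mitochondrially encoded genes (2 and 0 of 12, median 0.30). Jun, a subunit of the AP-1 transcription factor, was 2.34-fold higher (2.29 to 2.39). Icam1, an adhesion molecule, was 2.73-fold and mt-Co1, a subunit of the respiratory chain, 1.81-fold higher. Pmaip1, which promotes apoptosis, was 2.10-fold higher, and Bcl2a1d, which opposes it, 2.70-fold lower, with near-identical copies of Bcl2a1d in the genome.

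The other 17 lists did not stand apart in MAS against Control, and members of several moved both ways. The immune suppression and checkpoint list had 2 higher and 4 lower of 25 members (median -0.21): Cd274 and the scavenger receptor Olr1 (1.66-fold) were higher, and Ptgs2, Nt5e (2.01-fold, an enzyme that makes adenosine), the arginase Arg2 (1.57-fold, 604.5 and 384.7 CPM) and Hif1a (1.62-fold, the hypoxia transcription factor) were lower. Inflammatory cytokines and chemokines had 3 higher and 3 lower of 18 (median -0.03), with the chemokines Cxcl10 4.15-fold and Ccl5 10.6-fold higher, and Ccl4 2.01-fold and Il15 1.81-fold lower. Il1b, which encodes interleukin 1 beta, was at 4594 CPM in Control and 3881 in MAS. The tertiary granule and late maturation list had 2 and 2 of 17 (median -0.06). The protease inhibitor gene Stfa2l1 was 2.72-fold and Retnlg, a secreted resistin-like protein, 1.69-fold higher. Il1r2, a decoy receptor for interleukin 1, was 2.02-fold and the chemokine receptor Cxcr1 2.42-fold lower. In the cytokine receptor list (2 and 2 of 30, median -0.13) the signalling inhibitor Socs1 was 3.48-fold higher and Il1rap, a coreceptor of interleukin 1, 1.96-fold lower. Phagocytosis genes (2 and 2 of 14, median 0.03) included the lipopolysaccharide coreceptor Cd14, 1.72-fold, and the Fc receptor Fcgr4, 1.59-fold higher, with the integrin Itgax 2.21-fold and the kinase Syk 1.66-fold lower. Chemotaxis genes (3 and 0 of 21, median -0.03) included the integrin Itgb7, 4.49-fold higher, and the Toll-like receptor and inflammasome list (4 and 0 of 25, median -0.07) included the transcription factor Irf7, 2.38-fold, and the protease Casp1, 2.25-fold higher.

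Of the remaining lists, MHC class II had 1 higher and 0 lower of 4 measured members (median 0.24), too few to be called, with the protease Ctss 3.18-fold higher. The medians were 0.14 for primary granules (0 and 0 of 4), 0.02 for cell cycle (0 and 0 of 8), -0.05 for glycolysis and hypoxia (0 and 2 of 25), -0.13 for nuclear genes of oxidative phosphorylation (0 and 0 of 37) and -0.05 for ribosomal proteins (0 and 0 of 63). They were -0.13 for neutrophil ageing (1 and 1 of 13), 0.07 for granulocytic transcription factors (1 and 0 of 13), -0.04 for heat shock (0 and 0 of 14) and -0.06 for iron and haem (1 and 0 of 10). In those lists Klf2, a factor that restrains inflammatory genes, was 1.98-fold and the reductase gene Nqo1 (1.33 and 5.08 CPM) at least 1.5-fold higher, and Pfkfb3, a regulator of glycolysis, was 1.57-fold lower. The chemokine receptors Cxcr2 (904.3 and 883.7 CPM) and Cxcr4 (329.1 and 250.5 CPM) passed no rule. Arg1 (0.148 and 1.25 CPM) and Il10 (2.21 and 1.25 CPM) were near the floor. Tlr9, the receptor for CpG DNA, and the primary granule genes Mpo and Elane had at most 0.0741 CPM in both libraries.

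Equal weighting of the neutrophil clusters left out cluster 5 (led by Gbp genes, 1832 cells) and cluster 6 (led by Camp, Ngp and Ltf, 637 cells), because fewer than 50 of their cells were in Control or Resolution. In cluster 3 of that clustering stood 79 Control and 5269 MAS cells. This weighting ended the calls of Ngp (log2 ratio 0.72), Ltf (0.41), Gbp2 (0.80), Ifi47 (0.98), Cd274 (0.56) and Isg15 (0.36), and of all 12 named lower genes but Pid1 and Acta2. It also ended those of most named members of the lists and of the secondary granule (median 0.05), NF-kB (0.01) and survival (0.04) lists. Members that kept their calls included Jun, Ptgs2, Itgb7 and Zbp1, although Zbp1 fell from 2.18 to 0.73. Camp (1.52), Gbp5 (1.60), Gbp8 (2.34), Csta2 (1.83), H2-Q6 (3.20) and H2-Q7 (3.63) were brought down. TMM or RLE factors ended the calls of Arg2, Hif1a, Syk and Pfkfb3, an added 20 CPM those of Slc8a1, Nup155, Cnnm2 and Dock4 and of list members near the floor such as Cxcl10, Ccl5, Cxcr1 and Nqo1, leaving out cells above 2 times the median UMIs brought Ltf to 2.04, and keeping other cell types ended the calls of Thbs1, Ctss, Bcl2a1d and mt-Co1 and turned Cybb (-0.05), mt-Atp6 (-0.06) and the mitochondrial list (-0.20).

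**Figure D1:**
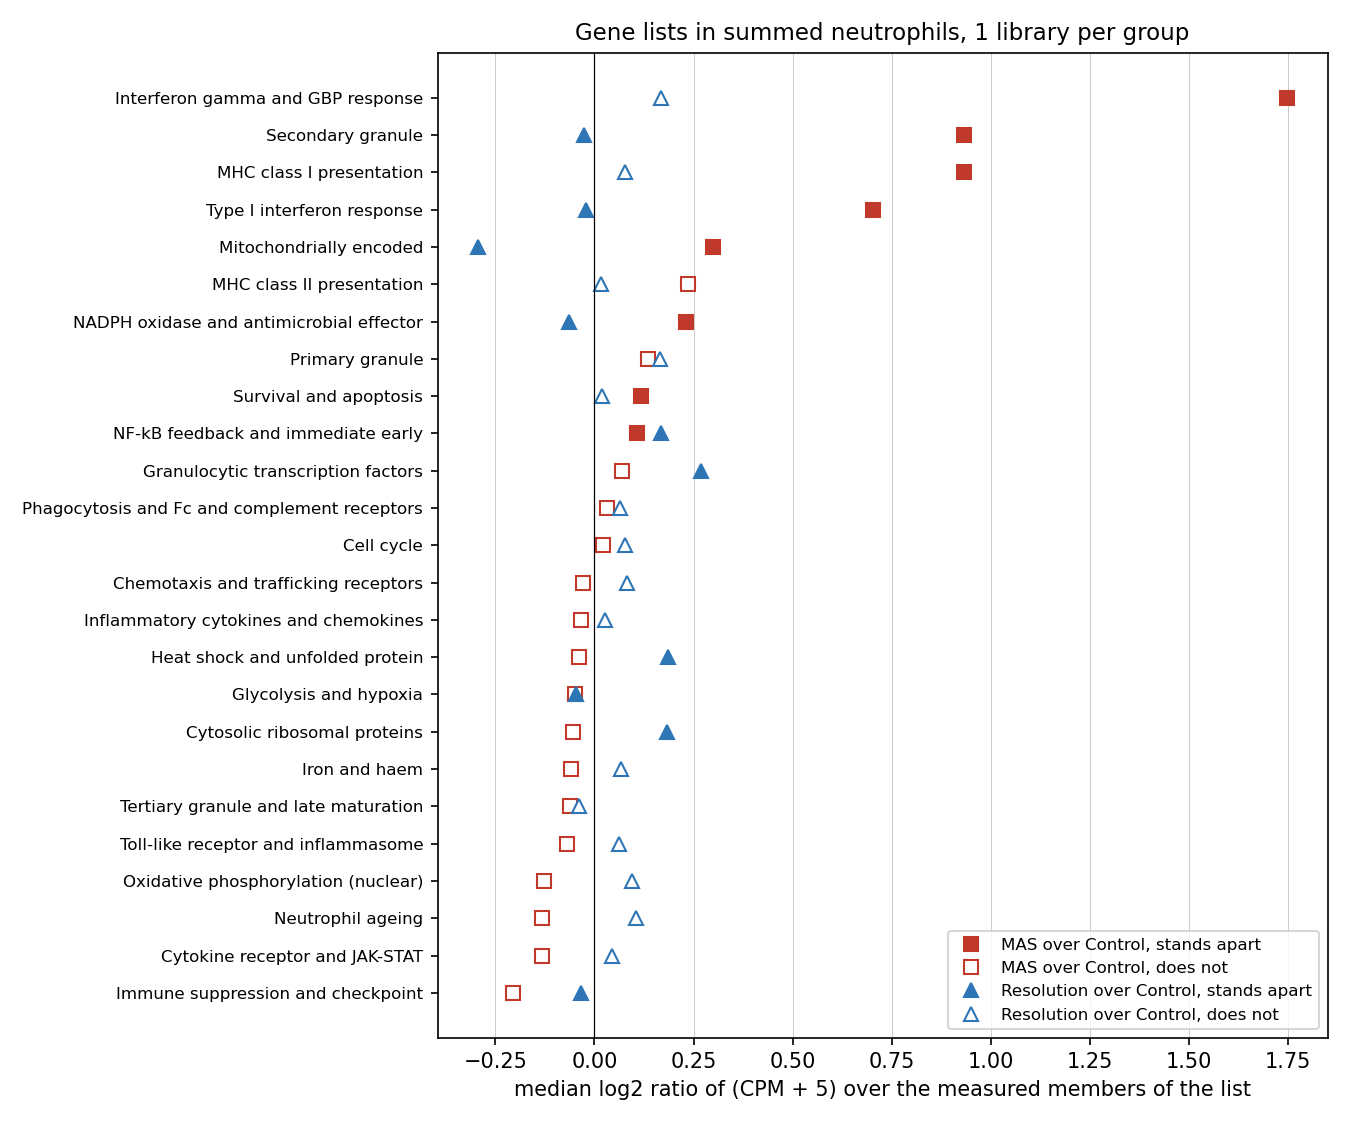
Median log2 ratio (horizontal axis) of each of the 25 gene lists in neutrophils, for MAS against Control (red squares) and Resolution against Control (blue triangles), with filled symbols for lists that stand apart from matched random lists. The interferon gamma list has the highest MAS median, 1.75, and a Resolution median of 0.17.

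**Figure D2:**
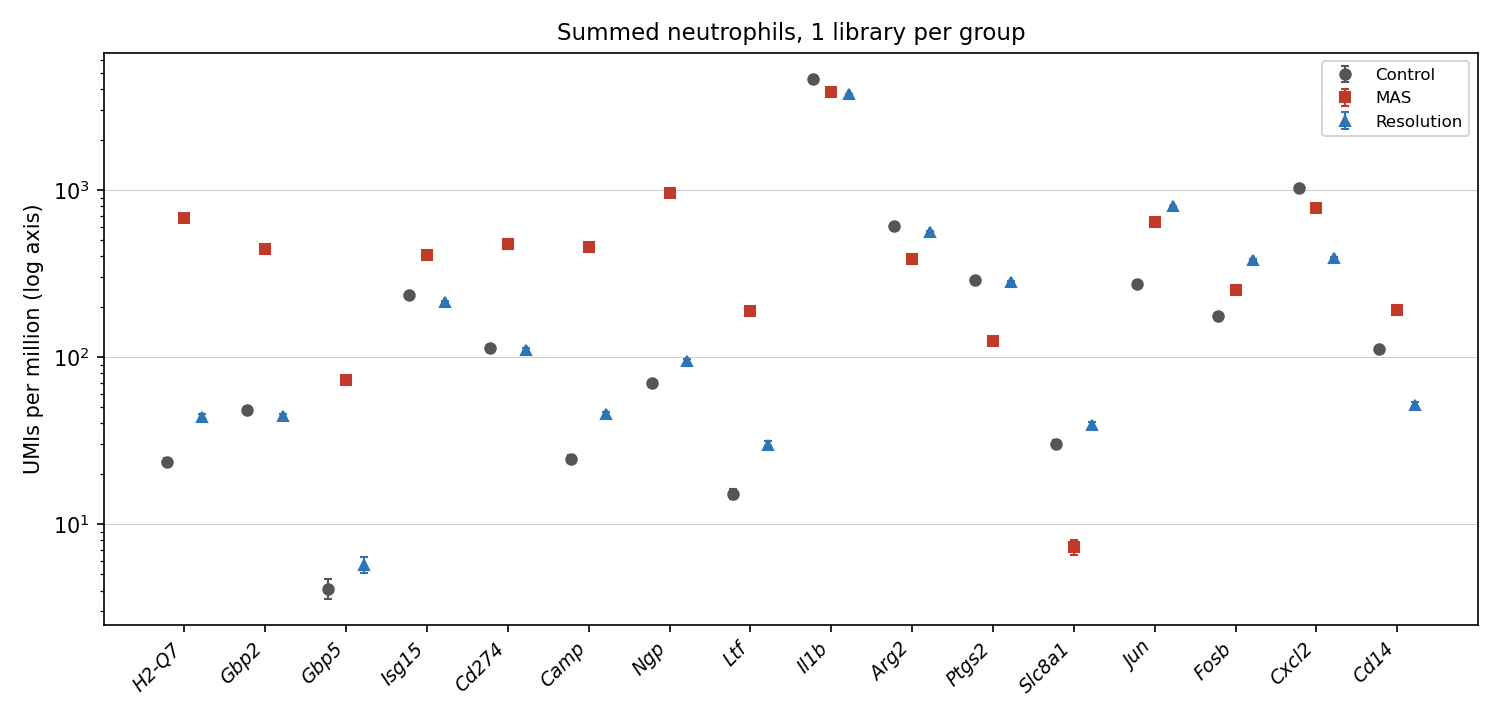
CPM (log axis) of 16 named genes in the neutrophil sums of the 3 libraries, with 95% exact Poisson intervals as bars. H2-Q7, Gbp2 and Camp stand highest in MAS, Slc8a1 and Ptgs2 lowest in MAS, and Cxcl2 and Cd14 lowest in Resolution.

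After 3 weeks of recovery, neutrophils differed from Control by 2-fold in few genes, and most of the transcripts higher in MAS stood near their Control level. Gbp2 was at 44.1 CPM in Resolution and 48.3 in Control, Cd274 at 110.6 and 113.4, and Isg15 at 213.4 and 234.9. Jun was 2.92-fold higher in Resolution than in Control (2.87 to 2.98; 273.3 and 798.7 CPM), and Fosb, another AP-1 subunit, 2.16-fold higher (2.11 to 2.22). Cxcl2, a chemokine that attracts neutrophils, was 2.63-fold lower (2.59 to 2.67; 1027 and 390.5 CPM), and Cd14 2.14-fold lower (2.05 to 2.23; 110.9 and 51.9 CPM).

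Of 6236 genes above the minimum, 4 were higher and 7 lower in Resolution than in Control (4 and 8 with TMM factors, 4 and 9 with RLE size factors), around a median log2 ratio of 0.09 that TMM factors moved to 0.02. The higher genes were Jun, Fosb, Rhob, a small GTPase of the cytoskeleton (2.24-fold, 2.18 to 2.30; 154.6 and 345.9 CPM), and Lrp1b. Among the lower genes were Cxcl2, Cd14, Nt5e (2.69-fold, 2.52 to 2.88; 55.8 and 20.7 CPM), Nr4a3, a nuclear receptor (2.99-fold, 2.61 to 3.43), and the gene models Gm28192 (2.39-fold) and Gm10076 (2.44-fold). Lrp1b, Nr4a3 and both gene models fall outside the naming rule and were chosen after their values were seen. Lrp1b, a lipoprotein receptor, was 3.22-fold higher (2.82 to 3.69; 5.28 and 17.0 CPM). Zeros made up 48.4% of its stored Control entries and a like share, 51.7%, of its stored Resolution entries. Jun lies on chromosome 4 at 95049034 to 95052222, Fosb on chromosome 7 at 19302696 to 19310051 and Rhob on chromosome 12 at 8497661 to 8500009. Cxcl2 lies on chromosome 5 at 90903871 to 90905938, Cd14 on chromosome 18 at 36725067 to 36726798 and Nt5e on chromosome 9 at 88327197 to 88372092.

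The lists above the random range in Resolution against Control were NF-kB and immediate early genes (5 higher and 0 lower of 30, median log2 ratio 0.17), granulocytic transcription factors (2 and 0 of 14, median 0.27), ribosomal proteins (0 and 0 of 63, median 0.18) and heat shock (0 and 0 of 14, median 0.19). Klf6 was 1.51-fold and Klf4 2.13-fold higher, both factors of myeloid differentiation. Below the random range, relative to the median gene, were mitochondrially encoded genes (0 and 0 of 12, median -0.29), NADPH oxidase and antimicrobial genes (0 and 1 of 14, median -0.06), glycolysis and hypoxia (1 and 0 of 25, median -0.05), immune suppression and checkpoint (0 and 2 of 25, median -0.03), secondary granules (2 and 3 of 17, median -0.03) and the type I interferon list (0 and 1 of 34, median -0.02). In these, Acod1 was 1.90-fold lower, the secreted protein gene Wfdc17 1.79-fold lower, Zbp1 1.67-fold lower, and Hk2, the first enzyme of glycolysis, 1.78-fold higher. Secondary granule genes moved both ways: Ltf was 1.96-fold and Camp 1.84-fold higher, while Lcn2, a siderophore-binding protein, was 1.57-fold (1641 and 1046 CPM) and the interferon-induced Ifitm6 1.78-fold lower.

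The interferon gamma list had 0 higher and 0 lower of 12 measured members in Resolution (median 0.17), and the MHC class I list 2 and 0 of 20 (median 0.08), with H2-Q6 2.43-fold and H2-Q7 1.86-fold higher than in Control. Cytokines and chemokines had 0 and 1 of 15 (median 0.03), cytokine receptors 1 and 1 of 30 (median 0.04; the receptor gene Il6ra 1.52-fold higher and Il1r2 1.53-fold lower), and survival 1 and 0 of 20 (median 0.02; Pmaip1 1.69-fold higher). Tertiary granule genes had 0 and 1 of 17 (median -0.04), phagocytosis 0 and 1 of 14 (0.07), Toll-like receptors and inflammasome 0 and 1 of 25 (0.06), ageing 0 and 1 of 13 (0.10) and iron and haem 0 and 1 of 9 (0.07). No member passed in primary granules (4 measured, median 0.17), cell cycle (8, 0.08), MHC class II (4, 0.02), chemotaxis (21, 0.08) or oxidative phosphorylation (37, 0.10). Cxcr2 was at 1.24-fold of Control, and Il1b was at 4594 and 3731 CPM in Control and Resolution, Arg2 at 604.5 and 562.7 and Cxcr4 at 329.1 and 340.8. Ngp was at 69.9 and 94.7 CPM, and Arg1, Il10, Tlr9, Mpo and Elane were below 3 CPM in both libraries.

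Thinning cells (log2 ratio -0.98) and keeping other cell types (-0.70) ended the 2-fold call of Cd14, as did leaving out cells above 2 times the median UMIs, an added 20 CPM also those of Nt5e, Ltf, Camp, Zbp1, H2-Q6 and H2-Q7, TMM or RLE factors those of Il6ra, Klf4 and Klf6, and keeping other cell types that of Fosb (log2 ratio 0.93), and it turned Klf4 (-0.13) and the ribosomal list (-0.02). Equal weighting, which left out the clusters led by Gbp genes and by Camp, Ngp and Ltf, ended the calls of Camp (0.02), Ltf (0.11), H2-Q6, Lcn2 and Il1r2 and of the transcription factor list (0.14), leaving out cells above 2 times the median UMIs raised Camp to 1.51, a CPM minimum of 50 turned the type I interferon list (0.01), and of the lists that stood apart only NF-kB and immediate early genes did so in all 17 settings.

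Compared directly with Resolution, MAS neutrophils had higher class I histocompatibility, interferon-induced and secondary granule transcripts. H2-Q7 was 15.5-fold higher in MAS than in Resolution (14.9 to 16.2), Gbp2 10.1-fold (9.66 to 10.5), Ngp 10.1-fold (9.78 to 10.3) and Camp 10.1-fold (9.68 to 10.5). Slc8a1 was 5.40-fold lower in MAS (4.84 to 6.03) and Pde7b 3.65-fold lower. Cd274 was 4.29-fold higher in MAS (4.17 to 4.41).

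Of 6258 genes above the minimum, 112 were higher and 58 lower in MAS than in Resolution, around a median log2 ratio of -0.21. TMM factors moved this median to 0.01 and the calls to 155 higher and 24 lower (161 and 24 with RLE size factors). Of the 112 higher genes 56 belonged to a fixed list. H2-Q6 was 17.4-fold higher and Gbp4, with 25 UMIs in Resolution, 149-fold (101 to 231). The other named lower genes were Amz1, a metalloprotease (3.96-fold), Pid1 (3.81-fold), Dock4 (3.26-fold) and Arhgap18 (3.03-fold), both of which act on small GTPases.

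Lists above the random range in MAS against Resolution were interferon gamma (18 higher and 0 lower of 19, median 1.64), secondary granules (14 and 0 of 18, median 1.10), MHC class I (17 and 0 of 21, median 0.91), type I interferon (21 and 1 of 37, median 0.73), mitochondrially encoded genes (6 and 0 of 12, median 0.51), NADPH oxidase and antimicrobial genes (4 and 0 of 14, median 0.34), cytokines and chemokines (5 and 4 of 18, median 0.10), survival (0 and 0 of 18, median 0.09) and chemotaxis (4 and 0 of 21, median 0.06). Some members were below 5 CPM in Resolution and measured only because they were high in MAS, which favours a higher list. They were 7 of the 19 interferon gamma, 3 of the 37 type I interferon and 3 of the 18 cytokine members. In the secondary granule and MHC class I lists 1 member each was such. Zbp1 was 8.28-fold higher in MAS, Isg15 1.92-fold, Acod1 3.40-fold and the lysozyme gene Lyz2 2.27-fold. Among members that were lower in MAS were the chemokine Ccl3 (2.08-fold) and Il15 (1.86-fold). No list stood apart as lower. Over all Resolution barcodes, 36.8% of stored mt-Atp6, 29.25% of mt-Co3 and 27.9% of mt-Co2 entries were zeros. This can lower the Resolution level of these mitochondrially encoded genes.

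Other lists had members that moved both ways. Immune suppression genes had 3 higher and 2 lower of 25 (median -0.18), with Wfdc17 2.28-fold higher and Ptgs2 2.26-fold lower in MAS. Tertiary granule genes had 3 and 2 of 17 (-0.05), with Retnlg higher (16270 and 6498 CPM in MAS and Resolution) and Csf3r, the receptor for the granulocyte growth factor, 1.63-fold lower. NF-kB and immediate early genes had 2 and 2 of 29 (-0.05), phagocytosis 2 and 1 of 14 (0.02; Cd14 3.67-fold higher), Toll-like receptors and inflammasome 4 and 2 of 25 (-0.11), cytokine receptors 2 and 2 of 30 (-0.22) and ageing 2 and 1 of 13 (-0.16; Cxcl2 2.00-fold higher). Iron and haem had 2 and 1 of 10 (-0.14; the iron exporter Slc40a1 1.73-fold lower), primary granules 1 and 1 of 4 (-0.03) and MHC class II 1 and 0 of 4 (0.17; Ctss 3.03-fold higher). Ribosomal proteins had 0 and 5 of 63 (-0.22), glycolysis 0 and 2 of 25 (-0.08; Hk2 1.93-fold lower), transcription factors 0 and 2 of 14 (-0.10), heat shock 0 and 1 of 14 (-0.20), oxidative phosphorylation 0 and 0 of 37 (-0.19) and cell cycle 0 and 0 of 8 (0.01).

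Equal weighting of the same 4 clusters, without those led by Gbp genes and by Camp, ended the calls of Slc8a1, Pde7b, Dock4, Arhgap18, Cd274 (log2 ratio 0.50), Isg15, Csf3r, Ccl3, Il15, Hk2, Slc40a1 and the survival list, and brought Camp to 1.499, Ngp to 1.18, Gbp2 to 1.27, Zbp1 to 1.31, Acod1 to 0.96, Ctss to 0.64, Gbp4 to 2.94, H2-Q7 to 2.59 and H2-Q6 to 2.67. TMM or RLE factors ended the calls of Csf3r and Slc40a1, leaving out cells above 2 times the median UMIs brought Camp to 2.22, keeping other cell types ended the calls of Ctss and Lyz2 and turned the mitochondrial (-0.14) and chemotaxis (-0.08) lists, and a CPM minimum of 50 turned the cytokine list (-0.07).

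The genes called in MAS were then followed into Resolution. Of the 100 genes higher in MAS than in Control, 88 were within 1.5-fold of Control in Resolution, 9 were at least 1.5-fold higher and 3 at least 1.5-fold lower, and the median log2 ratio was 0.02 against 1.60 in MAS. At 2-fold, 3 were higher again, where 0.0633 would be shared by independent sets of these sizes. Of the 45 genes lower in MAS, 36 were within 1.5-fold and 9 at least 1.5-fold lower, with a median of -0.03 against -1.16, and 2 were lower at 2-fold (0.0499 by independence). In 100 simulated pairs of unchanged libraries against the Control library, the median and the highest number called in both were 0. These draws hold counting error only and no spread between libraries, so 0 was fixed in advance and is no measure of the overlap without treatment. Part of the excess may come from the shared Control library, which cannot be divided.

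Cluster sizes were compared after the genes that differed by 2-fold had been left out of the clustering. Cluster 4, whose leading genes were Camp, Ngp and Ltf, held 0.456% (0.335 to 0.606) of Control, 7.13% (6.58 to 7.72) of MAS and 0.532% (0.403 to 0.689) of Resolution neutrophils, and 84.6% of its cells were MAS cells. Cluster 3, led by the interferon-induced Ifit3 and Gbp5, held 11.9% (11.3 to 12.5), 51.4% (50.3 to 52.5) and 10.6% (10.1 to 11.2). Cluster 1 held 45.9%, 8.49% and 57.3%, and cluster 2 held 41.8%, 33.0% and 31.5%. When genes that differed by 1.5-fold were left out too, the cluster closest to cluster 3 held 11.2%, 23.3% and 10.0%, and it shared only part of its cells (Jaccard index 0.492). With all variable genes kept, which let the differing genes define the clusters, the closest cluster held 0.214%, 22.2% and 0.336%. The latter shared few cells with cluster 3 (Jaccard index 0.264), so the change compares largely different cells. A cluster made mostly of 1 library may be that library and not a type of cell.

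Within clusters 1, 2, 3 and 4, 13, 13, 18 and 5 of 19 members of the interferon gamma list were at least 1.5-fold higher in MAS than in Control. The 19 members were taken by their CPM in the sums of these same cells, 8 of them only because they were high in MAS. That choice favours higher counts and medians within the clusters. Gbp2 was at 32.9 CPM in Control, 147.8 in MAS and 32.3 in Resolution in cluster 1, at 31.9, 133.8 and 28.8 in cluster 2, and at 169, 768.1 and 161.3 in cluster 3. Cd274 was at 126.7, 334.1 and 109.7 CPM in cluster 1, 68.4, 201.4 and 61.6 in cluster 2, and 230.1, 756.2 and 265.7 in cluster 3. H2-Q7 was at 24.4, 719.6 and 46.2 CPM in cluster 1 and at 2.57, 338.5 and 11.7 in cluster 4. The interferon gamma list had MAS against Control medians of 1.20, 1.22, 1.49 and 0.83 in clusters 1 to 4. Secondary granule genes had medians of 0.20, 0.19, 0.17 and 0.23, and cluster 4 held 96.0%, 98.6% and 97.4% of the Camp UMIs of Control, MAS and Resolution neutrophils.

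**Figure D3:**
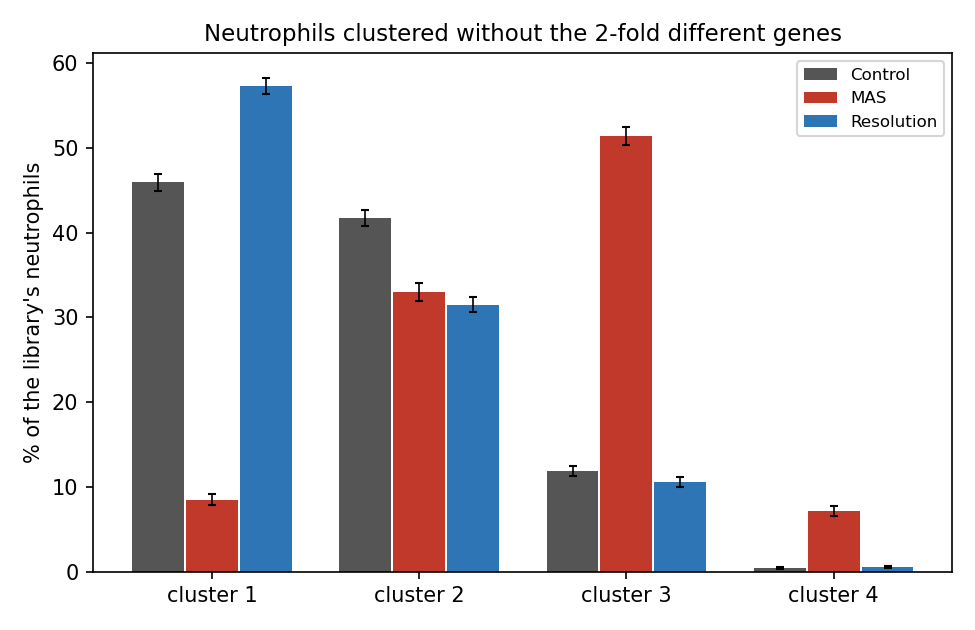
Share of neutrophils (percent, with 95% exact binomial intervals) in each of the 4 clusters made without the genes that differed by 2-fold, for the 3 libraries. Cluster 4 holds 7.13% of MAS neutrophils and under 1% of those of Control and Resolution.

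**Figure D4:**
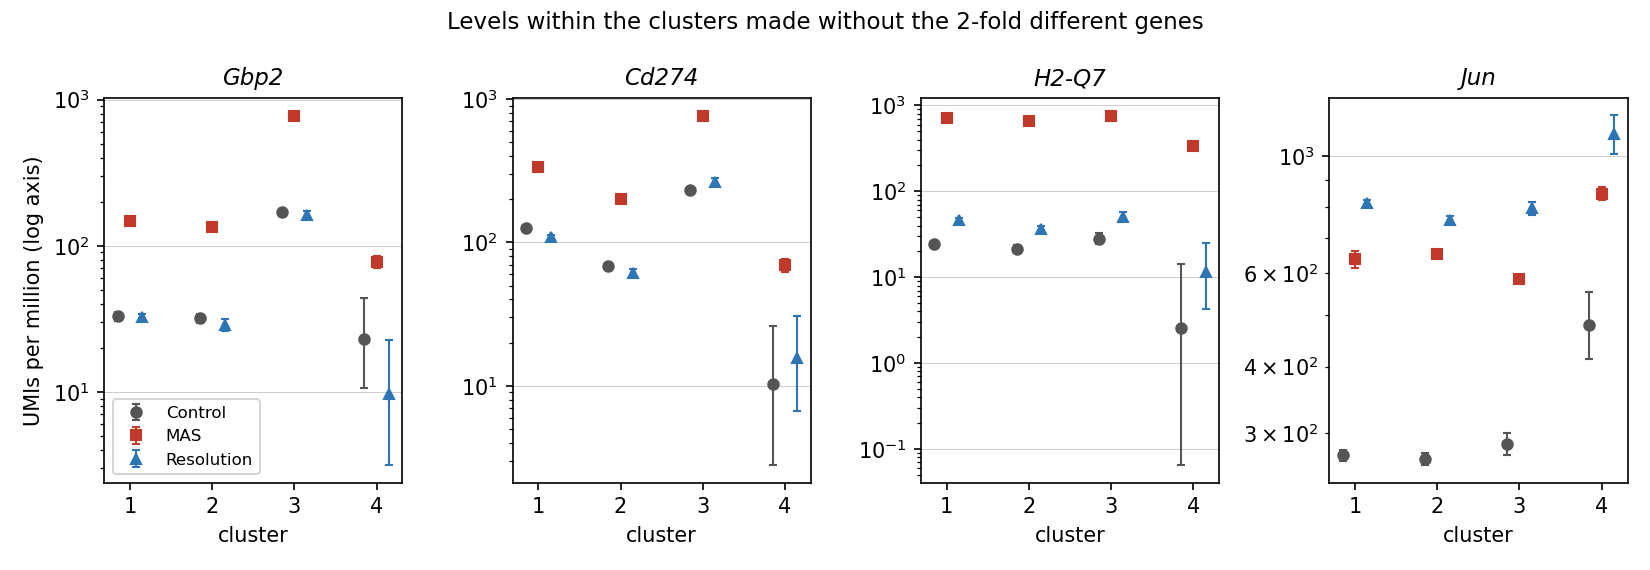
CPM (log axis, with 95% exact Poisson intervals) of Gbp2, Cd274, H2-Q7 and Jun within each of the 4 clusters for the 3 libraries. Gbp2, Cd274 and H2-Q7 stand highest in MAS in clusters 1, 2 and 3.

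Single cells were compared at equal depth for Camp and Cd274, a pair chosen from 8 genes after the values were seen. After thinning to 1000 UMIs, Camp was present in 0.233% (0.150 to 0.347) of Control, 2.84% (2.49 to 3.23) of MAS and 0.327% (0.228 to 0.455) of Resolution neutrophils. Entries stored as 0 count as absent here, and for Camp they numbered 1 in Control, 276 in MAS and 1 in Resolution neutrophils. In monocytes and macrophages Camp was present in 0 of 339, 85 and 242 cells, which allows up to 0.885%, 3.53% and 1.24%. At full depth the 48 MAS monocytes of cluster 11 held 0 Camp UMIs, which allows up to 0.0997 per cell, and the 37 MAS macrophages of cluster 13 held 8, against 2.98 per MAS neutrophil. Cd274 was present in 8.60% (8.07 to 9.16), 26.7% (25.7 to 27.7) and 8.53% (8.00 to 9.07) of neutrophils, against 1.47%, 4.71% and 1.65% of monocytes and macrophages, whose median depth before thinning was 12962, 18433 and 15100 UMIs against 4842, 5989.5 and 5010 in neutrophils. In platelets or megakaryocytes Cd274 was present in 5.71% (0.700 to 19.2) of 35 Control and 18.3% (10.1 to 29.3) of 71 MAS cells. Before shallower cells were left out, the median depth of this type was 1862 and 1200 UMIs. At Leiden resolution 2, a platelet or megakaryocyte cluster of 27 Control and 35 MAS cells held the median neutrophil marker at 1.03 times its share in all cells. Neutrophil RNA may thus lie behind these shares, so they cannot give the MAS background of Cd274, which stays open. Thinning left out 13, 12 and 17 neutrophils. The median thinned neutrophil held 4, 10.5 and 4 UMIs of MHC class I genes, 4, 7 and 3 of type I interferon genes, 0, 1 and 0 of interferon gamma genes and 7, 8 and 6 of secondary granule genes.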

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

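Of the tests below, only that of Jun, Fosb and Rhob in monocytes was set before its result was seen, and all other tests were chosen after the result was seen. The clusters of cells other than neutrophils enter no comparison, and those with a larger share of cells in MAS or Resolution than in Control, with intervals that do not overlap, are given here as values.

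Cluster 9, low in UMIs and led by haemoglobin genes in its summed counts, held 2.81% of MAS and 2.55% of Resolution cells, against 1.58% of Control. No erythroid marker passed the naming rule in it, so its share cannot be read as one of red cells. With no filter on barcodes, cells named erythroid numbered 1 in Control, 50 in MAS and 1 in Resolution. Cluster 12, the platelets or megakaryocytes, held 1.38% of MAS cells against 0.578% of Control. Cluster 13, macrophages with the serum amyloid gene Saa3, Prg4 and complement C1q genes, held 0.432% of MAS and 0.882% of Resolution cells against 0.165% of Control. Cluster 14, with immunoglobulin genes, Ccl5 and Gzma, held 0.379% of Resolution cells against 0.156% of Control. Cluster 15, with the liver transcripts Fabp1, Alb and Apoa2, held 0.560% of MAS cells (48 cells) and 0 of the Control cells, which allows up to 0.0275%. Cluster 16, led by Lrp1b and low in UMIs, held 0.339% of MAS cells against 0.0825% of Control.

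The first pattern weighed is the higher level of interferon gamma and GBP transcripts in MAS neutrophils. Free RNA fills droplets of all types. MAS cells of clusters 11, 13 and 14, with median depths at least that of MAS neutrophils, limit how much of it there can be. The most that they allow was 1.87 times the difference per neutrophil for the median member. It lay below the difference for only 4 of 19, so free RNA was not excluded. A different mix of the 4 clusters made without the 2-fold genes, with like levels within each, would leave the log2 ratios within clusters near 0. The lowest of the 4 within-cluster medians was 0.83. The members behind these medians were taken from the same cells, 8 of 19 only because they were high in MAS, which favours higher medians. That clustering left out the 17 genes of this list called higher at 2-fold, and Ly6a (log2 ratio 1.06), which was below the CPM minimum for a call. It thus cannot separate cells by these genes, and a mix of cells that differ in them stays open. In the clustering of all cells, the neutrophil cluster 7, led by Gbp genes, held 31 Control and 2305 MAS cells. With 1 library per group, treatment and any other difference between single libraries cannot be told apart. The response to CpG that the design names therefore stays open as a candidate explanation. So do free RNA, RNA of other cells, a different mix of cells that differ in these genes and a difference between libraries.

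The second pattern is the higher level of secondary granule transcripts in MAS neutrophils. The most free RNA that the same MAS cells allow lay below the difference per neutrophil for 8 of 11 members. This argues against free RNA as the whole difference for Camp, Ngp, Ltf and Itgb2l, whose limit came from cluster 11. It is weaker for Chil3, Cd177, Lyz2 and Mmp8, whose limit came from 22 cells of cluster 14. At Leiden resolution 2, the cluster with the same leading genes held only 12 MAS cells, so shallower cells may be among the 22 and lower the limit. At a median of 0.710 times the difference, free RNA as a part of the difference stays open, and as all of it for Cybb, Olfm4 and Serpinb1a. For entries stored as 0 to account for it, each such Control entry would have to hide 2.71 times the highest count of the gene in any Control neutrophil for the median member, which argues against them, although for Cybb (0.809) and Mmp8 (0.369) it was less than that count. Without cluster 4 the median was 0.25, which is consistent with a larger share of cluster 4 cells as a source, although leaving out a cluster led by such genes had to lower it, and Camp (1.05), Ngp (1.39) and Olfm4 (0.62) were still at least 1.5-fold higher and Lcn2 (-0.64) lower. Release of less mature neutrophils during the treatment may lie behind the larger cluster, and neither this nor a difference between single libraries was tested.

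The third pattern is the higher level of Jun, Fosb and Rhob in Resolution neutrophils, immediate early genes that can respond to the handling of cells. A difference in handling that acts alike on all cell types predicts at least 1.5-fold in the Ccr2 monocyte cluster, where Fosb was at 1.11 times Control (1.03 to 1.19), Jun at 1.44 (1.38 to 1.51) and Rhob at 1.42 (1.29 to 1.56). The NF-kB and immediate early list stood higher in those monocytes too (median log2 ratio 0.20, against 0.17 in neutrophils), so a smaller effect shared by the cell types stays open. A different mix of the 4 clusters made without the 2-fold genes was argued against for Jun and Rhob. Their lowest within-cluster ratios were 2.29 (1.94 to 2.72) and 2.17 (2.08 to 2.27). It stays open for Fosb, whose lowest was 1.68 (1.32 to 2.15) in cluster 4, with 47 Control cells, and 1.91 or more in clusters 1 to 3. That clustering left out Jun, Fosb and Rhob, so it cannot separate cells by these genes. A different mix of cells that differ in them therefore stays open. At Leiden resolution 2 of all cells, a neutrophil cluster led by Tgm3, Fosb and Jun held 367 Control and 1198 Resolution cells. Handling that acts more on neutrophils than on monocytes could explain the pattern, as could a lasting effect of the treatment or a difference between single libraries, and these were not tested.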

How the results depend on the processing

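Of the alternatives, 3 were chosen after seeing the data (cells above 1% haemoglobin or above 2 times the median UMIs left out, and entries stored as 0 counted as 1). The doublet alternative gave no value, because the detector marked 1 cell in all. No paired analysis was possible because each group is 1 library. Of 5344 values of single genes under alternatives, 5048 kept their call at 1.5-fold (higher, lower or neither), 291 gained or lost one and 5 reversed. Of 1275 values of lists, 1210 kept standing apart or not, 57 changed this and 8 reversed. Equal weighting (68 values) and RLE factors (41) moved most single genes. Gene counts stayed within 1.5 times the main count in 69 of 108 cases and list counts in 97 of 102. The type I interferon, interferon gamma, MHC class I and NADPH oxidase lists stood apart as higher in MAS than in Control in all 17 settings (medians 0.37 to 0.87, 0.84 to 2.59, 0.59 to 1.16 and 0.19 to 0.41). Several settings could hardly change whether a list stands apart. Scaling factors move a list and its random lists almost alike, and the filters on barcodes and on haemoglobin left out few neutrophils.

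For MAS against Control, the main count was 100 genes higher and 45 lower. The count of higher genes was 54 with 20 CPM added, 61 with a CPM minimum of 50, 55 with neutrophil clusters weighted equally, 209 at 1.5-fold and 51 at 3-fold. The count of lower genes was 24 with TMM factors, 23 with RLE size factors, 89 with 1 CPM added, 15 with 20 CPM added, 28 with the minimum of 50, 10 with clusters weighted equally, 314 at 1.5-fold and 2 at 3-fold. Lists standing apart as lower went from 0 to 1 with other cell types kept and to 1 with clusters weighted equally. Keeping other cell types turned the mitochondrial list (-0.20), Cybb (-0.049) and mt-Atp6 (-0.065).

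For Resolution against Control, the main count was 4 genes higher and 7 lower, so small shifts change it. The count of higher genes was 61 with other cell types kept, 7 with cells thinned, 13 with 1 CPM added, 10 with clusters weighted equally, 47 at 1.5-fold, 0 at 3-fold and 9 with entries stored as 0 counted as 1. The count of lower genes was 11 with other cell types kept, 4 with cells thinned, 11 with 1 CPM added, 1 with 20 CPM added, 66 at 1.5-fold and 0 at 3-fold. The type I interferon list turned at the CPM minimum of 50 (0.011), and keeping other cell types turned the ribosomal list (-0.017) and Klf4 (-0.13).

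For MAS against Resolution, the main count was 112 genes higher and 58 lower. The count of higher genes was 62 with 20 CPM added, 68 with the minimum of 50, 65 with clusters weighted equally, 233 at 1.5-fold and 56 at 3-fold. The count of lower genes was 24 with TMM and 24 with RLE factors, 146 with 1 CPM added, 20 with 20 CPM added, 38 with the minimum of 50, 18 with clusters weighted equally, 532 at 1.5-fold and 4 at 3-fold. Lists standing apart as lower went from 0 to 1 with other cell types kept, 1 with cells thinned and 3 with clusters weighted equally. The cytokine list turned at the minimum of 50 (-0.071), the chemotaxis list with other cell types kept (-0.084), at the minimum of 50 (-0.12) and with clusters weighted equally (-0.021), and the mitochondrial list with other cell types kept (-0.14). Equal weighting turned Icam1 (-0.14) and Lcn2 (-0.0020).

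Counts at other folds, minimums and added CPM differ by construction. Equal weighting left out 2 of 6 clusters with fewer than 50 cells in a library, the Gbp-led cluster 5 (1832 cells) and the Camp-led cluster 6 (637 cells), whose cells were then not in the sums. It gives 79 Control cells in cluster 3 and 77 MAS cells in cluster 4 the weight of far larger clusters of the other library, in clusters that the differing genes helped to define. For the other shifts the cause was not tested.

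Cells other than neutrophils made up 6.54% of MAS cells, and 7.19% with no filter on barcodes. With genes that differed by 1.5-fold left out of the clustering, the cluster closest to cluster 1 held 41.3% of Control, 27.9% of MAS and 52.9% of Resolution neutrophils (Jaccard index 0.670). That closest to cluster 2 held 46.2%, 39.3% and 36.0% (0.709), and that closest to cluster 3 held 11.2%, 23.3% and 10.0% (0.492). With all variable genes kept, the closest clusters held 37.6%, 1.46% and 45.2% (Jaccard index 0.682), then 51.2%, 2.77% and 42.7% (0.569), and 0.214%, 22.2% and 0.336% (0.264, so most cells differ from those of cluster 3). Cluster 4 moved by less than its interval in both.

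Depth limits the shares of single cells. With cells thinned to 2000 UMIs, Camp was present in 0.391% of Control, 3.74% of MAS and 0.470% of Resolution neutrophils, and at 500 UMIs in 2.17% of MAS neutrophils, while without thinning the shares were 0.679%, 6.60% and 0.971%. Cd274 was present in 14.3%, 37.0% and 13.8% at 2000 UMIs, 4.77%, 16.9% and 4.88% at 500 and 24.4%, 53.8% and 24.9% without thinning. More molecules per cell give larger shares by construction, and MAS stood highest at each depth.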

Other observations

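All tests and choices in this part were chosen after the result was seen, the monocyte cluster and its CPM minimum of 50 included. Monocytes with Ccr2 and F13a1, cluster 11 of all cells, differed in the same libraries. They numbered 321 in Control, 48 in MAS and 142 in Resolution, with 4223774, 805134 and 1994041 UMIs, so the MAS values rest on few cells. In MAS monocytes Gbp2 was 3.81-fold higher than in Control (3.06 to 4.74), Cd274 2.73-fold (1.92 to 3.84) and H2-Q7 3.08-fold, while Isg15 was 1.40-fold lower. The interferon gamma list had 7 of 10 measured members at least 1.5-fold higher and 0 lower (median log2 ratio 0.99), and the type I interferon list 2 higher and 3 lower of 29 (median -0.29), where neutrophils had a median of 0.70. MHC class I had 5 of 17 members higher (median 0.44), MHC class II 4 of 9 (median 0.44) and NF-kB and immediate early genes 9 of 23 (median 0.42), with 0 lower in each. The primary granule list had 3 of 6 members higher and 0 lower (median 0.84) and the secondary granule list 6 higher and 3 lower of 12 (median 0.66).

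In Resolution monocytes, MHC class II genes, which present antigen to helper T cells, had 4 of 8 members higher than in Control and 0 lower (median 0.88). The tertiary granule and late maturation list had 7 of 14 higher and 0 lower (median 0.65), the immune suppression and checkpoint list 4 and 0 of 16 (median 0.23), and NF-kB and immediate early genes 1 and 2 of 22 (median 0.20). Below the random range were MHC class I (median -0.18), secondary granule (-0.16), nuclear oxidative phosphorylation (-0.14) and mitochondrially encoded genes (-0.20). Cd14 was 1.70-fold lower, against 2.14-fold lower in neutrophils, and Cxcl2 was at 1.16 times Control (0.948 to 1.42) where neutrophils had it lower. No difference between the cell types was tested.

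Among neutrophils, cluster 10 of all cells, led by the stefin and cystatin A genes Cstdc5, Stfa2 and Stfa1, held 132 Control, 429 MAS and 90 Resolution cells. In the clustering with all variable genes kept, 416 MAS neutrophils (5.20%) stood in the clusters that held most Control and Resolution neutrophils, and 143 Control (1.39%) and 156 Resolution (1.46%) neutrophils stood in those that held most MAS neutrophils. Of the 416 MAS cells, 1 shared its barcode with a Control and 2 with a Resolution cell.

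Entries stored as 0 were not spread evenly. Of the stored Camp entries, 34.3% were zeros in MAS neutrophils and 1.41% in Control, and of the Ngp entries 35.6% and 3.36%. For H2-K1, a classical class I histocompatibility gene, 13.6% were zeros in Control, 0.288% in MAS and 14.2% in Resolution neutrophils. Counting entries stored as 0 as 1 ended the MAS against Control call of mt-Atp6, whose log2 ratio went from 0.64 to 0.47.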
